A study of Rattus norvegicus with 48 samples.

How the data were processed

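Poly(A) RNA was sequenced from rat peripheral blood mononuclear cells (PBMC) and from the orbitofrontal cortex (OFC), a prefrontal region, with 24 libraries per tissue. Per the labels' protocols, libraries were made from 91 ng of RNA with the NEBNext Ultra II Directional kit and 13 PCR cycles. Dams received lipopolysaccharide (LPS), a bacterial cell wall component that activates innate immunity, at 50 µg/kg on gestational days 15 and 16, or saline. Offspring received delta-9-tetrahydrocannabinol (THC), the main psychoactive compound of cannabis, or vehicle from postnatal day 30 to 40. The daily THC dose was 2.5 mg/kg up to day 32, 5 mg/kg on days 33 to 36 and 10 mg/kg on days 37 to 40, per the labels.

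The deposited values are expected counts, the raw fragments that the authors assigned to each gene in each library, not scaled to depth. TopHat and Cuffdiff are named in the submitters' processing notes without versions, and per the file headers the OFC columns are those of a Cuffdiff read-group table. The genome build, the gene annotation and the strand setting are not given in the sources used here. Between 0.58% and 1.1% of the values per library were not whole (tolerance 1e-06), so all values were rounded to whole numbers before testing. The OFC values came in 4 tables, 1 for each combination of maternal and adolescent treatment with both sexes in it, whereas the PBMC values came in 1 table. Treatment in OFC therefore coincides with the table, and if the tables were quantified in separate runs the treatment and the run cannot be told apart. The OFC tables also hold 16 per-library value columns that were not used here.

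Libraries were mapped to groups by the labels' titles. OFC columns name the group and not the animal, so libraries within an OFC group are called a, b and c. By the numbers in the titles, 38 animals gave the 48 libraries and 10 animals gave both tissues, but OFC libraries could not be matched to them. No litter is given in the sources used here. Animals of 1 litter share maternal treatment, so p-values for maternal LPS measure the spread between animals and not between litters.

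Genes with a status flag or with 2 identifiers were left out, 20 in PBMC and 14 in OFC. Among the OFC genes, 5 were flagged HIDATA and listed at 0 in every library, and 9 others held the 15 values flagged FAIL. In PBMC, 4 of the 5 HIDATA genes had a mean of over 100 fragments, and the 5 together held 1.82% of the fragments on average.

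Testing was done per tissue with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr on the 8 groups, which left 12836 genes in PBMC and 15033 in OFC. Libraries were scaled with TMM, and 1 mean per group was fitted with glmQLFit, so that all 24 libraries of a tissue shared the estimate of the spread. Contrasts of these means were tested with glmQLFTest. Every adjusted p in the text is from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested, unless another test is named, and genes with an adjusted p under 0.05 are said to have passed. Main effects average over the other factors. Log2 fold changes are LPS over saline, THC over vehicle, or female over male. CPM, fragments of a gene per 1000000 fragments of the library, were computed with the TMM-scaled totals and are given as mean ± SD. The common biological coefficient of variation was 0.306 in PBMC and 0.161 in OFC. Principal components were computed from log2 CPM with a prior count of 2.

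The 10 comparisons per tissue, their tests and the alternatives were fixed before the data were examined. The rule fixed for naming genes took, per comparison, passing genes with a mean of at least 1 CPM by fold change and, where fewer than 6 passed, the 3 smallest p-values in each direction. Fixed gene lists, 41 in all, including cell type markers, were to be tested by symbol with camera and fry. The files pair the gene identifiers with no symbols, and 0 of the identifiers matched the gene table given (47357 genes, assembly GRCr8). The gene lists and cell type markers were therefore not tested, and gene functions are not described. At most 2 rising and 2 falling identifiers are printed per comparison in the Results, and further sex genes in the additional observations. Those in the Results were taken by smallest p, after the values were seen. For the sex comparison the order in OFC was used for both tissues.

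The alternatives fixed in advance were the DESeq2 1.42.0 Wald test, RLE in place of TMM, no filter on low counts, 1 surrogate variable from sva 3.50.0 as a covariate, and leaving out each library in turn. Chosen after seeing the data were the share of fragments in the 10 most abundant genes as a covariate, PBMC tests without the genes listed at 0 in whole groups, PBMC tests without the 3 libraries with under 14000 genes detected, and, for differences between the tissues, each library left out in turn and the ratio of mean CPM, with SE by the delta method. For each comparison, 60 splits of the libraries, the real one included, were tested with group labels shuffled. Effects in the 2 tissues were compared with a z test on the 2 fold changes and their SE for 5 genes, leaving out genes with a mean of 3 fragments or fewer in a group of either tissue. Relations across genes were compared with 100 labellings within each sex, the real one included.

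The pipeline was tested on simulated counts drawn from the real means and totals. Only genes with a mean of at least 2 CPM were changed, and counts were drawn independently, with no structure shared between genes within a library. The recovery rates therefore do not hold for genes under 2 CPM, and the false calls do not allow for such structure. In the simulated maternal LPS comparison, edgeR recovered 32.8%, 91% and 100% of 1.5-, 2- and 4-fold changes in PBMC (12655 genes tested, 5 false calls), and 91%, 98.5% and 100% in OFC (14936 genes, 14 false calls). In the simulated interaction of LPS and THC, it recovered 6%, 32.8% and 78.8% in PBMC (12631 genes) and 29.9%, 86.6% and 98.5% in OFC (14929 genes). For simulated LPS alone, it recovered 4.5%, 62.7% and 87.9% in PBMC (12630 genes) and 70.1%, 98.5% and 100% in OFC (14942 genes). The DESeq2 test on the simulated maternal LPS comparison made 21 false calls in PBMC (12836 genes) and 29 in OFC (15033 genes). It was given only genes left by the low-count filter there, but all genes of the real counts. Its simulated false calls therefore do not carry over directly to the real DESeq2 counts. Tables were handled with Python 3.11.15 and pandas 2.3.3, permutation tests with scipy 1.17.1 and numpy 2.4.6, the camera test with limma 3.58.1, and plots with matplotlib 3.10.9.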

Results

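Gene expression was measured in blood and brain of rat offspring in a design that crossed maternal immune activation, adolescent cannabinoid exposure and sex. Each tissue had 8 groups of 3 libraries, from female and male offspring of LPS- or saline-treated dams that were given THC or vehicle in adolescence. PBMC are the lymphocytes and monocytes of blood, and the OFC is a cortical region. In units of 1000000 fragments in genes, PBMC libraries held 4.34 to 13.96 (median 10.27) and OFC libraries 19.67 to 26.65 (median 23.53). Female PBMC libraries held 8.60 ± 2.36 and male ones 11.87 ± 1.31 in the same unit (SD, n = 12 each), with overlapping ranges of 4.34 to 12.93 and 9.38 to 13.96. The first principal component held 28.8% of the variance in PBMC and 31.1% in OFC. In PBMC it set apart 1 library, female LPS and THC replicate 2, at a score of 156.3, while the libraries of the other groups ranged from -26.3 to 47.9.

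**Figure D1:**
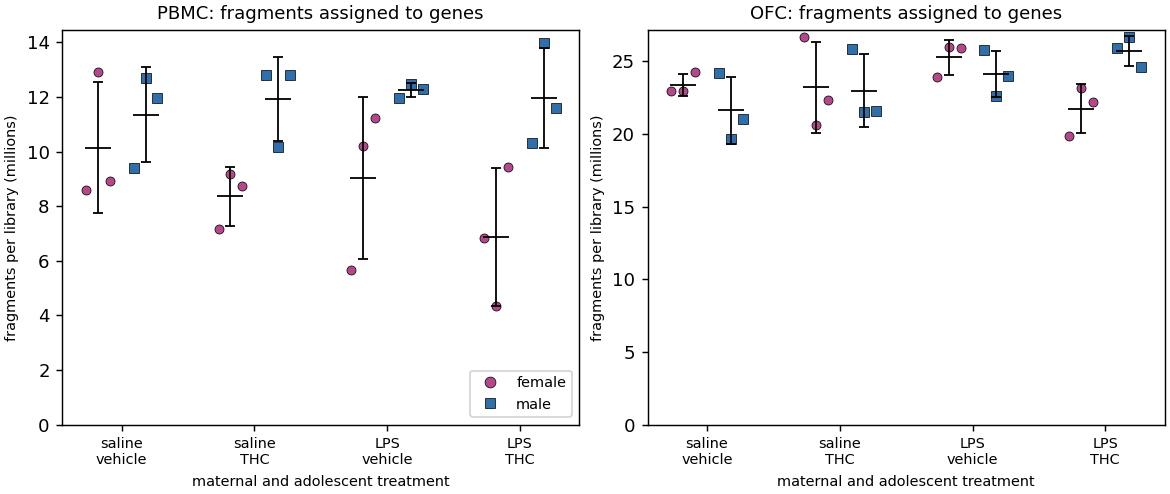
Fragments assigned to genes per library, in units of 1000000, by maternal and adolescent treatment in PBMC and OFC. Points are libraries (circles female, squares male), and bars are the mean and SD of 3; the PBMC libraries span 4.34 to 13.96 and the OFC libraries 19.67 to 26.65.

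The sex comparison asked which genes differed between females and males across the treatments, and it also tests the sex labels. In both tissues a small set of genes separated the sexes with no overlap between libraries. ENSRNOG00000057231 stood at 227 ± 36.7 CPM in male PBMC and 0.476 ± 0.714 CPM in female PBMC, and at 76.5 ± 6.09 against 0.0174 ± 0.0279 CPM in OFC (SD, n = 12 per sex). ENSRNOG00000060048 stood at 101 ± 11.4 CPM in male and 0.219 ± 0.252 CPM in female PBMC, and at 70.3 ± 4.96 against 0.0293 ± 0.0281 CPM in OFC. In the other direction, ENSRNOG00000051257 was at 19.9 ± 8.99 CPM in female and 0.921 ± 0.696 CPM in male PBMC, and at 14.8 ± 5.87 against 0.0598 ± 0.0522 CPM in OFC. ENSRNOG00000060793 was higher in females by a similar amount in both tissues, with a log2 fold change of 0.61 (SE 0.06) in PBMC and 0.63 (SE 0.05) in OFC.

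Adjusted p-values for these 4 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 6.09e-17, 3.22e-17, 2.1e-07 and 7.07e-06 in PBMC, in the order named. In OFC the same test gave 2.51e-19, 3.3e-22, 1.73e-11 and 2.7e-08. In each case all 12 libraries of one sex lay above all 12 of the other. In PBMC 8 genes passed, 2 higher in females and 6 higher in males. In OFC 11 passed, 4 higher in females and 7 higher in males, and they included all 8 of the PBMC genes in the same direction. Another 3 passed in OFC alone, and the sex difference of 1 of these differed between the tissues (adjusted p = 2.34e-12, z test on the 2 fold changes). For the second the same z test passed (adjusted p = 0.00111) but not when the ratio of mean CPM replaced the fitted fold (adjusted p = 0.124), and its call in OFC was lost in 16 of 29 alternative settings. For the third the z test did not pass (adjusted p = 0.105), and its call in OFC was lost in 17 of 29 alternative settings. DESeq2 passed 22 genes in PBMC.

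**Figure D2:**
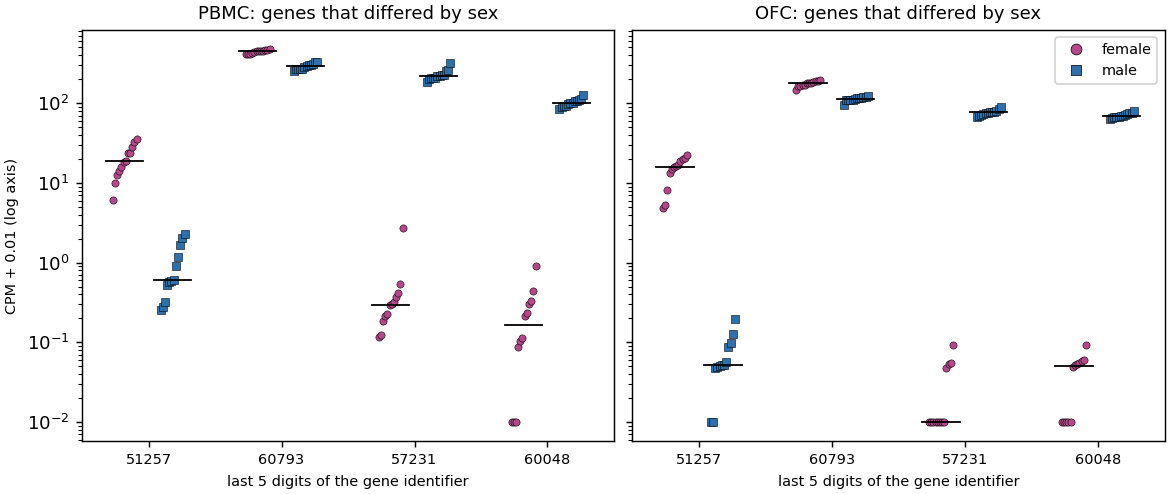
CPM plus 0.01 per library on a log axis for 4 genes that differed by sex, in PBMC and OFC, with the last 5 digits of each identifier on the horizontal axis. Points are libraries ordered by value (circles female, squares male) and lines are medians of 12; no female and male points overlap within a gene.

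Maternal LPS was compared with maternal saline in PBMC over both adolescent treatments and both sexes. None of the 12836 genes passed in edgeR's quasi-likelihood test, with 695 genes at an unadjusted p under 0.05 (17 of 60 splits of the libraries, the real one included, had as many), and DESeq2 passed 12, 3 higher and 9 lower after LPS. The smallest p-values belonged to genes of low or moderate expression. ENSRNOG00000047574 was at 0.441 ± 0.623 CPM after LPS and 3.8 ± 2.83 CPM after saline, and ENSRNOG00000005772 at 8.75 ± 3.67 against 16.4 ± 5.17 CPM (SD, n = 12 each, both adjusted p = 0.3 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among higher values after LPS, ENSRNOG00000053527 was at 1.07 ± 0.871 against 0.0729 ± 0.124 CPM and ENSRNOG00000030158 at 1.31 ± 0.782 against 0.307 ± 0.228 CPM (both adjusted p = 0.381). With the share of the 10 most abundant genes as a covariate 2 genes passed, both lower after LPS. The same number and direction held without the 3 libraries with the fewest genes detected. Both settings were chosen after the data were seen. In female LPS vehicle libraries the share counts 2 genes listed at 0 in all other PBMC libraries, so it is not comparable between libraries.

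Adolescent THC was compared with vehicle in PBMC in the same way, and 1 gene passed. ENSRNOG00000054582 was listed at 0 fragments in all 12 THC libraries and held 106 to 702 fragments in all 12 vehicle libraries, 31.4 ± 14 CPM (SD, n = 12). Against a floor of 3 fragments over the THC group this is at least 1286.9-fold lower, with an adjusted p of 3.76e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The zeros coincided exactly with treatment in both sexes and after both maternal treatments. Other PBMC genes were listed at 0 in whole groups as well. ENSRNOG00000047321 held 70656 to 142473 fragments in the 3 female LPS vehicle libraries and 0 in the remaining 21 libraries, and ENSRNOG00000058105 was also above 0 in that group alone. An exact 0 of this kind can be a value that was not returned, so these levels are given as listed.

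**Figure D3:**
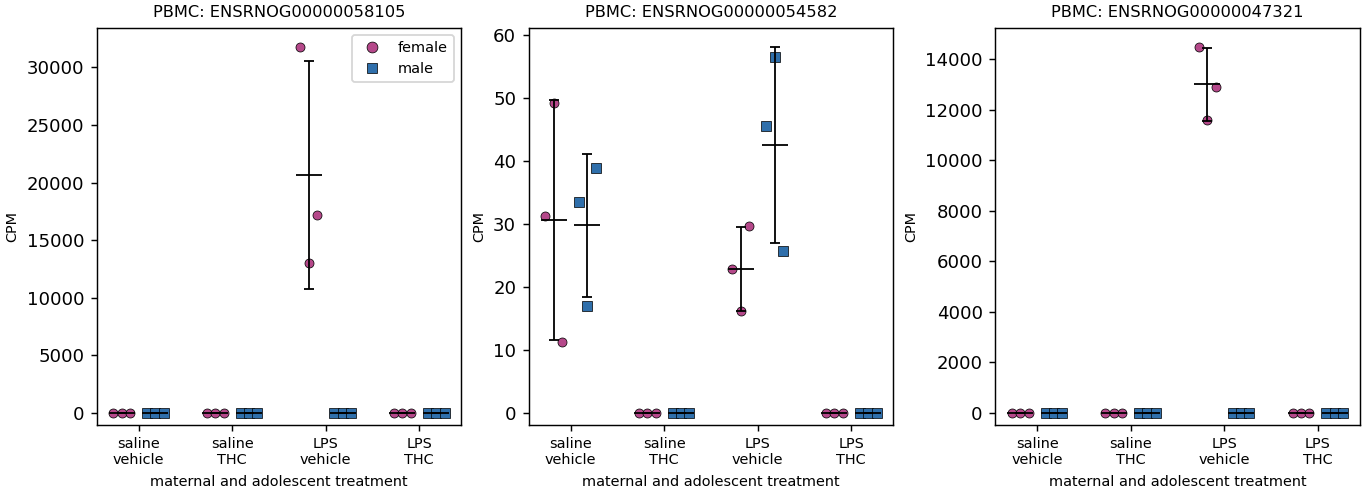
CPM per PBMC library for the 3 genes listed at 0 in whole groups, by maternal and adolescent treatment. Points are libraries (circles female, squares male), and bars are the mean and SD of 3; ENSRNOG00000054582 is at 0 in all 12 THC libraries and the other genes are above 0 in the female LPS vehicle group alone.

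Apart from that gene, none passed for THC in PBMC. There were 629 genes at an unadjusted p under 0.05 (18 of 60 splits of the libraries had as many), of which 442 were higher and 187 lower after THC, and DESeq2 passed 2 genes, both lower. ENSRNOG00000046258 was at 38.7 ± 12 CPM after THC and 23.7 ± 4.64 CPM after vehicle, and ENSRNOG00000042367 at 2.45 ± 1.26 against 0.928 ± 0.649 CPM (SD, n = 12 each). Neither passed, with an adjusted p of 0.574 for both in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the share of the 10 most abundant genes as a covariate, chosen after the data were seen, 39 genes passed, 37 higher and 2 lower after THC. In female LPS vehicle libraries this share counts ENSRNOG00000047321 and ENSRNOG00000058105, listed at 0 in all other PBMC libraries. The share is therefore not comparable between PBMC libraries. Without the genes listed at 0 in whole groups, 0 passed with edgeR, with 641 at an unadjusted p under 0.05.

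The combined design asks whether maternal LPS alters the response to THC, and whether each exposure alone or both together differ from no exposure. For the interaction of LPS and THC in PBMC, 0 genes passed with edgeR or DESeq2 and 503 had an unadjusted p under 0.05. LPS alone against no exposure gave 0 genes with edgeR, 223 at an unadjusted p under 0.05 and 1 with DESeq2. THC alone and both exposures against no exposure each gave 1 gene with edgeR, again ENSRNOG00000054582, which was at 0 in the 6 exposed libraries and at 30.2 ± 14 CPM in the 6 saline vehicle libraries (SD). DESeq2 passed 2 genes for THC alone and 19 for both exposures, 9 higher and 10 lower. ENSRNOG00000010515 was at 71.5 ± 9.76 CPM after both exposures and 45.9 ± 7.03 CPM without exposure (SD, n = 6 each, log2 fold change 0.64, SE 0.13), and did not pass in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.204).

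Interactions with sex asked whether females and males responded differently in PBMC, and no gene passed with edgeR. Maternal LPS by sex gave 0 genes, with 323 at an unadjusted p under 0.05 and 0 with DESeq2. THC by sex gave 0, with 558 and 0, and the interaction of all 3 factors gave 0, with 374 and 1. Among genes with a more positive THC log2 fold change in females than in males, ENSRNOG00000004870 had the smallest p. The difference of its log2 fold changes was 1.60 (SE 0.41, adjusted p = 0.881 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

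In OFC, maternal LPS was followed by a change in 5 of 15033 genes over both adolescent treatments and both sexes, 2 higher and 3 lower. ENSRNOG00000015382 rose from 5.95 ± 1.06 CPM after saline to 8.9 ± 1.66 CPM after LPS, a log2 fold change of 0.57 (SE 0.08), and 7 of 12 LPS libraries lay above every saline library. ENSRNOG00000020078 rose from 2.53 ± 0.516 to 4.06 ± 0.796 CPM, a log2 fold change of 0.68 (SE 0.11). ENSRNOG00000001872 fell from 0.388 ± 0.198 to 0.0733 ± 0.0614 CPM, and 11 of 12 LPS libraries lay below every saline library. ENSRNOG00000015248 fell from 0.503 ± 0.308 to 0.122 ± 0.133 CPM (SD, n = 12 each). Both of these falling genes had few fragments. ENSRNOG00000001872 had at most 5 in an LPS and 21 in a saline library, and ENSRNOG00000015248 at most 13 and 33. The remaining gene fell from 5.37 ± 1.67 to 1.13 ± 1.36 CPM, and 10 of 12 LPS libraries lay below every saline library.

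Adjusted p-values were 0.00576 for ENSRNOG00000015382, 0.0205 for ENSRNOG00000001872 and 0.0242 for the other 3 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The unadjusted p was under 0.05 for 1922 genes, and 8 of 60 splits of the libraries, the real one included, had as many. ENSRNOG00000015382 passed in all 29 alternative settings, including each library left out, while ENSRNOG00000020078 passed in 13, ENSRNOG00000001872 in 22 and ENSRNOG00000015248 in 17. DESeq2 passed 39 genes, 18 higher and 21 lower, which included all 5, and 1 surrogate variable left 1. The count fell to 1 without female LPS vehicle b, male LPS THC a, male saline THC a or male saline vehicle b, and was 9 without female LPS vehicle a. The values of each combination of maternal and adolescent treatment came in a table of their own.

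**Figure D4:**
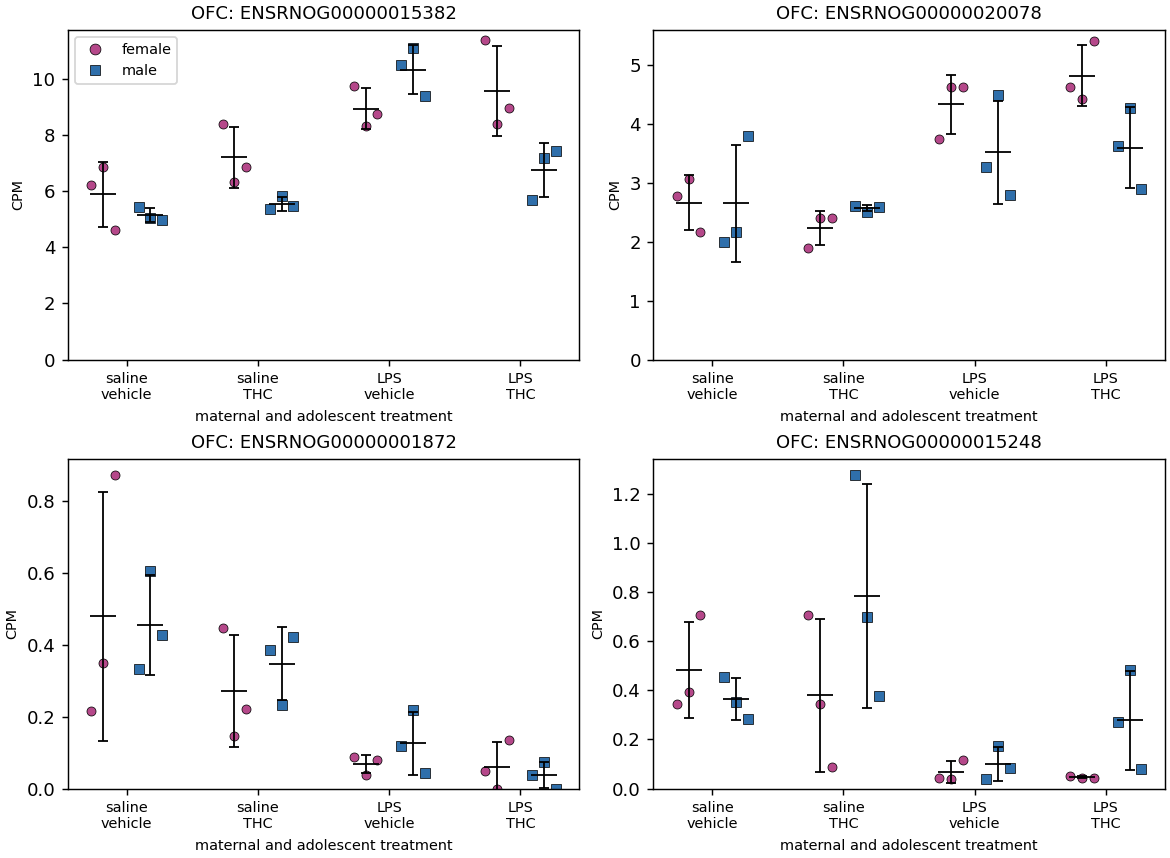
CPM per OFC library for 4 genes that passed for maternal LPS, by maternal and adolescent treatment. Points are libraries (circles female, squares male), and bars are the mean and SD of 3; ENSRNOG00000015382 and ENSRNOG00000020078 are higher and ENSRNOG00000001872 and ENSRNOG00000015248 lower after maternal LPS.

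LPS alone was set against no exposure in the OFC of vehicle-treated offspring. ENSRNOG00000015382 rose from 5.53 ± 0.855 CPM in the saline vehicle libraries to 9.63 ± 1.04 CPM in the LPS vehicle libraries (SD, n = 6 each), with all 6 LPS libraries above all 6 saline libraries. Its log2 fold change was 0.80 (SE 0.11), and it was the 1 gene that passed (adjusted p = 0.00725 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An unadjusted p under 0.05 was found for 4017 genes (26.7% of those tested), 1801 higher and 2216 lower after LPS. With 1 surrogate variable this fell to 626 genes, and ENSRNOG00000015382, at a log2 fold change of 0.77 (SE 0.13), no longer passed (adjusted p = 0.0915). ENSRNOG00000033654 was at 0.281 ± 0.0833 against 0.713 ± 0.0996 CPM and ENSRNOG00000001156 at 36.3 ± 4.48 against 27.5 ± 2.17 CPM (n = 6 each), both with an adjusted p of 0.133. DESeq2 passed 107 genes, 53 higher and 54 lower.

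The 10 most abundant genes held 7.22% ± 1.87 of the fragments in the LPS vehicle libraries, 5.70% ± 0.93 in the saline vehicle, 5.75% ± 0.92 in the LPS THC and 5.68% ± 0.83 in the saline THC libraries (SD, n = 6 each). The 10 genes were taken per library. The HIDATA genes, listed at 0 in OFC, are left out of this share and of its total. The first principal component followed this share over the 24 OFC libraries (Pearson's r = 0.72, permutation p = 0.00011, adjusted 0.00022; Spearman's rho = 0.61, permutation p = 0.00196, adjusted 0.00392; both two-sided), and r was 0.55 without the 2 libraries farthest from the median. In PBMC the HIDATA genes kept their fragments and could be among the 10, so the share is not the same measure. Its relation to the first principal component there had r = 0.59 (permutation p = 0.0135, adjusted 0.0135) and rho = 0.41 (permutation p = 0.045, adjusted 0.045). Without the 2 PBMC libraries with the share farthest from the median r was 0.59. Female LPS and THC replicate 2, at a first principal component of 156.3, was not left out there. In female LPS vehicle libraries the PBMC share counts 2 genes listed at 0 in all other PBMC libraries. With the OFC share as a covariate, chosen after the data were seen, 924 genes had an unadjusted p under 0.05 for LPS alone in OFC. ENSRNOG00000015382 then had a log2 fold change of 0.78 (SE 0.12) and an adjusted p of 0.0695. Without female saline vehicle c, 2017 genes had an unadjusted p under 0.05.

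Adolescent THC in OFC was followed by no gene that passed with edgeR. The unadjusted p was under 0.05 for 1902 genes (8 of 60 splits of the libraries had as many), and DESeq2 passed 24 genes, 14 higher and 10 lower after THC. ENSRNOG00000012495 was at 42.4 ± 5.76 CPM after THC and 32.2 ± 2.91 CPM after vehicle, with 10 of 12 THC libraries above every vehicle library (log2 fold change 0.39, SE 0.07). ENSRNOG00000008587 was at 24.2 ± 1.96 against 19.8 ± 2.24 CPM, and ENSRNOG00000014003 at 11.4 ± 0.877 against 13.3 ± 1.25 CPM (SD, n = 12 each). Adjusted p-values were 0.104, 0.305 and 0.305 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without male saline THC a, 1 gene passed.

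The interaction of LPS and THC in OFC gave 0 genes with edgeR and with DESeq2, and 1486 at an unadjusted p under 0.05. ENSRNOG00000010158 had an interaction of 1.12 on the log2 scale (SE 0.23) and ENSRNOG00000053753 one of 0.95 (SE 0.20), both with an adjusted p of 0.473 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. THC alone against no exposure gave 0 genes with edgeR and DESeq2 and 606 at an unadjusted p under 0.05. For both exposures against no exposure, edgeR passed 0 genes, 824 had an unadjusted p under 0.05 and DESeq2 passed 12, 5 higher and 7 lower. ENSRNOG00000001872 was at 0.0494 ± 0.0505 CPM after both exposures and 0.467 ± 0.237 CPM without exposure, and ENSRNOG00000017767 at 10 ± 1.4 against 5.42 ± 1.65 CPM (SD, n = 6 each, both adjusted p = 0.169 in the same edgeR test). Without female LPS THC c, 3 genes passed.

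No gene passed for a different response of females and males in OFC. Maternal LPS by sex gave 0 genes with edgeR, 511 at an unadjusted p under 0.05 and 0 with DESeq2. THC by sex gave 0, with 465 and 0, and the interaction of all 3 factors gave 0, with 418 and 0. ENSRNOG00000013738 had the smallest p for THC by sex, a difference of log2 fold changes of 0.64 (SE 0.13, adjusted p = 0.979 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without male LPS vehicle c, 3 genes passed for THC by sex and 1 for the interaction of all 3 factors.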

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

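The comparisons of the tissues below were chosen after the results were seen. Among genes that passed for a main effect and were tested in both tissues, effects on 5 were compared with a z test, with Benjamini-Hochberg adjustment over the 5. The other 7, all sex genes, had a mean of 3 fragments or fewer in 1 sex in at least 1 tissue and were not compared, since their fitted fold depends on the prior count. The test treats the tissues as independent, although 10 animals gave both. A gene taken because it passed in 1 tissue tends to have an overstated fold there, and the test does not allow for this.

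ENSRNOG00000015382 was higher after maternal LPS in OFC (log2 fold change 0.57, SE 0.08), while in PBMC its log2 fold change was -0.25 (SE 0.22). The difference, OFC minus PBMC, was 0.82 (SE 0.23, adjusted p = 0.00111, z test), in a gene taken because it passed in OFC. With the ratio of mean CPM in place of the fitted fold it was 0.86 (SE 0.34, adjusted p = 0.0266). The negative fold in PBMC came from 1 library, female saline vehicle 2 at 204 CPM. Without it the PBMC fold was 0.01 (SE 0.17) and the difference 0.56 (SE 0.18, adjusted p = 0.00363). With each of the 48 libraries left out in turn the difference ranged from 0.56 to 0.98 and passed each time. OFC values came in 1 table for each treatment combination and PBMC values in 1 table, and litters are not given. A difference between tables or litters was therefore not separated from LPS.

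Of the 4 sex genes compared, 2 had unequal fitted folds in the tissues, and 1 of them also had unequal ratios of mean CPM. ENSRNOG00000037911 was higher in females by a log2 fold change of 2.23 (SE 0.24) in OFC and 0.22 (SE 0.14) in PBMC, a difference of 2.01 (SE 0.28, adjusted p = 2.34e-12, z test), or 2.05 (SE 0.27, adjusted p = 1.32e-13) by the ratio of mean CPM. In OFC it was at 3.06 ± 1.41 CPM in females and 0.634 ± 0.229 CPM in males, with 11 of 12 females above every male. ENSRNOG00000059207 was lower in females, by -2.74 (SE 0.49) in OFC and -0.82 (SE 0.28) in PBMC, a difference of -1.92 (SE 0.56, adjusted p = 0.00111, z test). Its levels in OFC were close to 0, at 0.157 ± 0.184 CPM in females and 0.57 ± 0.306 CPM in males, against 5.31 ± 3.07 and 8.95 ± 4.15 CPM in PBMC (SD, n = 12 each). By the ratio of mean CPM the log2 folds were -1.86 (SE 0.54) and -0.75 (SE 0.31), and the difference of -1.11 (SE 0.62) did not pass (adjusted p = 0.124). Its call in OFC was kept in 13 of 29 alternative settings, so a tissue difference for this gene is not established. Among the genes not compared, ENSRNOG00000051257 had a log2 fold change of 4.43 (SE 0.37) in PBMC and 7.88 (SE 0.38) in OFC, a difference that was not tested. No other technical explanation was tested for these differences.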

How the results depend on the processing

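The share of the 10 most abundant genes as a covariate, PBMC tests without the genes listed at 0 in whole groups and PBMC tests without the 3 libraries with under 14000 genes detected were chosen after seeing the data, as were the ratio of mean CPM and each library left out for differences between the tissues. RLE scaling left all 20 counts of passing genes within 1.5 times, and no gene reversed its direction in a comparison for which the naming rule took it. The PBMC fold of ENSRNOG00000015382 for maternal LPS, outside that rule, went from -0.25 to 0.01 without female saline vehicle 2. The tissue difference of ENSRNOG00000060793 for sex, 0.02, became -0.01 without male LPS vehicle 2 or male saline THC 2 in PBMC. The cause of the changes below was not tested, except that tests without the genes listed at 0 drop the gene in question.

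With DESeq2, the counts differed in 12 of 20 comparisons, and in 11 by over 1.5 times. In PBMC they became 12 for maternal LPS, 2 for THC, 22 for sex, 1 for the interaction of all 3 factors, 1 for LPS alone, 2 for THC alone and 19 for both exposures. In OFC they became 39 for maternal LPS, 24 for THC, 107 for LPS alone and 12 for both exposures, and for sex 15 in place of 11, within 1.5 times. Without a filter on low counts, 10 genes passed for maternal LPS in OFC. With 1 surrogate variable, 1 passed for maternal LPS in OFC and 0 for LPS alone (edgeR; 626 at an unadjusted p under 0.05; DESeq2 without a covariate passed 107). With the share of the 10 most abundant genes as a covariate, 2 passed for maternal LPS, 39 for THC and 2 for LPS alone in PBMC. In OFC 2 passed for maternal LPS and 0 for LPS alone (924 at an unadjusted p under 0.05). The PBMC share counts 2 genes that were listed above 0 in the female LPS vehicle libraries alone, so it is not comparable between PBMC libraries. The OFC share leaves out the HIDATA genes, which were listed at 0 there. Without the genes listed at 0 in whole groups, PBMC counts for THC, THC alone and both exposures were 0 with edgeR, with 641, 545 and 950 genes at an unadjusted p under 0.05. Without the 3 PBMC libraries with the fewest genes, 2 passed for maternal LPS.

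Leaving out each library in turn moved 23 of 480 counts by over 1.5 times. In OFC the count for maternal LPS ranged from 1 to 9: 1 without female LPS vehicle b, male LPS THC a, male saline THC a or male saline vehicle b, 2 without female saline THC b or female saline vehicle c, 3 without female LPS THC c, female LPS vehicle c, female saline THC a or male saline vehicle a, and 9 without female LPS vehicle a. It ranged from 0 to 1 for THC (1 without male saline THC a), from 9 to 12 for sex, from 0 to 3 for THC by sex, 0 to 1 for the interaction of all 3 factors and 1 to 2 for LPS alone (the highest without male LPS vehicle c in these 3). For both exposures it ranged from 0 to 3, with 3 without female LPS THC c and 1 without male LPS THC c or male saline THC c. In PBMC it ranged from 1 to 2 for THC (2 without male saline THC 1), 8 to 10 for sex, 1 to 2 for THC alone (2 without female saline THC 2 or male saline THC 1) and 1 to 3 for both exposures (3 without female LPS THC 3, 2 without female saline vehicle 2). All other ranges were 0 to 0.

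Where a library is left out, 2 libraries remain in its group and the shared estimate of the spread carries the test. The camera and fry tests of the gene lists, with preset and estimated correlation, were not run, since the identifiers could not be paired with symbols. In simulated maternal LPS comparisons, 32.8% of 1.5-fold changes were recovered in PBMC (12655 genes) and 91% in OFC (14936 genes). The changed genes had a mean of at least 2 CPM. PBMC had both fewer fragments and a larger spread, and the simulations did not vary these separately. No paired analysis was possible because the OFC columns carry no animal numbers and the replicate numbers in PBMC only count animals within a group.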

Other observations

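Tests of values not returned for whole groups, silencing by THC, combined exposure and genes on and off in both tissues were chosen after the result was seen. The covariate for the most abundant genes was tested after the result with 1 surrogate variable had been seen, and the genes listed at 0 in whole groups were taken out of the on and off genes after a first count. The counts at an unadjusted p under 0.05 in the splits, other than for LPS alone in OFC, were also summarized after the results were seen. The other tests were chosen before their results were seen.

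Some genes were close to absent in some animals and well expressed in others. A gene was counted when its third-highest library had at least 2 CPM and at least 3 libraries lay 10 times or more below that level, with at least 20 of 24 libraries either that low or within 2-fold of the level, genes that differed by sex aside. There were 25 such genes in PBMC and 11 in OFC. Of these, 5 were the same gene in both tissues, where 0.015 is expected from 18 and 10 genes among the 11683 tested in both (one-sided Fisher's exact p = 1.19e-12). The expected number takes all tested genes as equally able to meet the rule. The overlap concerns genes and not animals. Whether the state belongs to the animal was not tested, since OFC libraries could not be matched to animals. An inherited variant or a difference from the reference genome might give such states, but the cause was not tested. ENSRNOG00000033517 was off in 7 of 12 saline and 0 of 12 LPS libraries in PBMC, and in 5 of 12 saline and 0 of 12 LPS libraries in OFC. The other shared genes did not split in this way. In LPS and saline libraries of PBMC they were off in 5 and 3, 8 and 6, 10 and 8, and 7 and 7. In OFC the numbers were 8 and 5, 6 and 6, 8 and 7, and 6 and 9, in the same order of genes.

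If such states were inherited and treatment groups were drawn from few litters, the states would follow maternal treatment. In PBMC, 4 of the 25 on and off genes had an exact Fisher p under 0.05 between LPS and saline, reached by 1 of 100 labellings within sex, the real one itself (highest other 2), which suggests that families may differ between the maternal treatments. In OFC, 1 of 11 genes did, as in 21 of 100 labellings (highest other 2). By adolescent treatment the counts were 0 in PBMC (highest other 4) and 0 in OFC (highest other 1), and all 100 labellings reached them. The litter is not given in the sources used here, so a litter difference and an effect of LPS on these genes cannot be separated.

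ENSRNOG00000054582 was at 0 in every PBMC THC library and at 106 fragments or more in every vehicle library. In a search for fragments assigned to another gene, 0 genes were at least 10 CPM higher in THC libraries without overlap. Fragments spread over several genes, or assigned to a gene that varies widely between libraries or was left out before testing, would not show in it. Fragments assigned elsewhere are therefore not excluded. Values not returned for whole groups in the quantification stay possible. There were 2 other PBMC genes at 0 in every library of whole groups, with over 100 fragments in every library of another group of the same sex. Those 2 held 70656 to 190239 fragments, in the female LPS vehicle group alone, against at most 702 for ENSRNOG00000054582. They are too unlike this gene to show that its zeros arose in the same way. Silencing by THC exposure cannot be told apart from values that were not returned. The gene reached only 9 fragments in OFC vehicle libraries and 5 in OFC THC libraries.

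Female LPS and THC replicate 2 stood apart in PBMC, with a first principal component of 156.3 and 12179 genes detected. Its depth is argued against as the whole cause, since other PBMC libraries thinned to its total detected 13065 or more genes (median 13988). Combined exposure is also argued against, since the other 2 libraries of the group, at -7.7 and -8.5, lay inside the range of the other groups. A low number of starting molecules is consistent with the gaps: for genes expected at 2 to 5 fragments the estimated number of fragments per molecule was 5.42, and 6.75 and 8.14 for genes expected at 5 to 10 and 10 to 20. The bound set for the other libraries, under 1.5, was wrong, since all of them lay above it and female saline THC 1 reached 4, so the measure is graded.

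The broad shift in OFC after LPS alone, 4017 genes at an unadjusted p under 0.05, exceeded all other splits (1 of 60 as high, the real one, highest other 3242), so chance is argued against for this comparison taken alone. It is 1 of 20 comparisons, and in each of the others at least 7 of 60 splits had as many genes at an unadjusted p under 0.05 as the real one. For maternal LPS and for THC in OFC, with 1922 and 1902 genes, it was 8 of 60 each (highest other 3335 and 6325), so chance was not excluded for those counts. With the share of the 10 most abundant genes as a covariate 924 genes were left, so the shift went along with this share. The share leaves out the HIDATA genes. Fragments taken by a few genes would lower the others together, but TMM scaling removes such a common drop. The 1801 higher and 2216 lower among the 4017 genes therefore cannot decide on that cause. The share followed the first principal component (Pearson's r = 0.72) and was higher in the LPS vehicle group. As a covariate it removes part of any LPS effect too. ENSRNOG00000015382 kept a log2 fold change of 0.78 (SE 0.12) against 0.80 (SE 0.11) without the covariate, and its call ended (adjusted p = 0.0695, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) as the SE grew and the fold fell slightly. With 1 surrogate variable, fixed in advance as an alternative, 626 genes were left, and the gene's fold was 0.77 (SE 0.13, adjusted p = 0.0915). Blood or immune cells in the tissue cannot be told apart: the 623 genes at least 16 times higher in PBMC had a median log2 fold change 0.05 above the others (camera p = 0.0858 with a preset correlation of 0.01, p = 0.447 with an estimated correlation). An effect of maternal LPS stays open, as does a difference between the 4 tables in which OFC values came.

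The effect of maternal LPS was compared across groups, as Pearson's r across genes, which are not independent replicates, over 100 labellings with the real one included. Between vehicle and THC animals r was 0.13 in PBMC (17 of 100 as high, highest other 0.43) and 0.14 in OFC (25 of 100, highest other 0.61). Between females and males it was 0.18 in PBMC (6 of 100, highest other 0.26) and 0.41 in OFC (5 of 100, highest other 0.52). Between PBMC and OFC it was 0.23 over 11683 genes (18 of 100, highest other 0.38). None of the 5 relations had a share under 5 of 100, and that of females and males in OFC lay at this limit, so a shared response there stays open.

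Of 60 splits of the libraries, only the real one called as many genes for sex in PBMC (8 genes, highest other 0) and in OFC (11, highest other 1), for maternal LPS in OFC (5, highest other 0) and for LPS alone in OFC (1, highest other 0), so chance is argued against for these 4 of 20 counts, each taken alone. The shares are not adjusted over the 20 comparisons, and the splits move single animals, so a difference between litters is not tested by them. For LPS alone in OFC, the edgeR count of 1 fell to 0 with 1 surrogate variable and with the share of the 10 most abundant genes. In these settings 626 and 924 genes had an unadjusted p under 0.05. The log2 fold change of ENSRNOG00000015382 was 0.77 (SE 0.13) and 0.78 (SE 0.12), against 0.80 (SE 0.11) without a covariate. DESeq2 passed 107 genes without a covariate and was not run with one. For THC in PBMC 4 of 60 splits called as many genes (1 gene, highest other 581), for THC alone 3 (1 gene, highest other 1) and for both exposures 3 (1 gene, highest other 189). Chance was not excluded for these 3 counts, and the tallies of any called gene do not test ENSRNOG00000054582 itself, which separated all 12 THC from all 12 vehicle libraries (adjusted p = 3.76e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Where no gene was called, all 60 splits reached the count of 0. The highest other counts there were 22 for maternal LPS, 0 for LPS by THC, 0 for LPS by sex, 128 for THC by sex, 1 for all 3 factors and 1 for LPS alone in PBMC. In OFC they were 4511 for THC, 406 for LPS by THC, 4352 for LPS by sex, 4527 for THC by sex, 1 for all 3 factors, 235 for THC alone and 1989 for both exposures. Some splits thus called many more genes than the real one, and what those splits have in common was not tested.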
